A study of Homo sapiens with 4 samples.

How the data were processed

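Polysome-associated RNA was sequenced from HCT116 cells, a human colorectal carcinoma line. Cytoplasmic extracts of wild type cells and of cells labelled as a Dicer1 knockout were separated on sucrose gradients, and each gradient gave a heavy library (mRNAs with 10 or more ribosomes) and a light library (9 or fewer). There were 4 libraries, 1 per group, in 2 gradients. The deposited table holds whole-number read counts per gene symbol, not normalised by the authors as far as the values show, since the library totals differ. Per the submitters' processing notes, CASAVA, STAR and HTSeq and the genome build hg19 were used; their versions, the annotation and the strand setting are not given in the sources used here. Without the strand setting, reads of overlapping genes on opposite strands cannot be assigned with certainty.

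The table lists 26364 gene symbols, of which 7814 had no count in any library. Symbols were matched to GENCODE release 44 (GRCh38), directly for 23035 and through older symbols for the remainder of the 24424 matched. GENCODE served for gene types, coding and 3′ UTR lengths, 3′ UTR sequences and GRCh38 positions. All counts stayed those made on hg19. No column of the table was left without a sample. Library totals ran from 17457116 to 20933675 counts. With 3 counts taken as the most that a count of 0 allows, the floor was 0.143 to 0.172 CPM. Intervals and floors are 95% limits and cover counting error only, because reads without molecular identifiers are not independent molecules.

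For heavy against light polysomes, edgeR 4.0.16 in R 4.3.3 fitted the counts with TMM scaling, filterByExpr and a quasi-likelihood test with the gradient as a block. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 2 gradients served as replicates of the fraction contrast. With 1 residual degree of freedom, edgeR shared 1 spread trend across genes, so that the spread is the disagreement between the genotypes and the p-values rest on it. Gene lists were tested on this fit with limma 3.58.1, by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry.

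The genotype comparison has 1 library on each side in each fraction and so no replicate check, and no p-value was computed for a gene or a list in it. The permutation p-values given for microRNA sites compare families of microRNAs with each other and do not test the genotype. Log2 ratios of TMM-scaled CPM (counts scaled to equal library size), with a prior count of 2, were given with counting intervals. Genes were counted where the labelled knockout and the wild type differed at least 2-fold in the same direction in both fractions, among genes with at least 100 counts in the higher library of each pair. The shift was the log2 heavy to light ratio of the labelled knockout minus that of the wild type. It was counted at 2-fold or more, with a counting interval that excluded 0, among genes with at least 50 counts in each library. The median of each gene list was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, and a list stood apart below the 2.5th or above the 97.5th percentile. These percentiles describe the libraries and are not tests of the conditions. Genes with a 7-nucleotide microRNA site in the 3′ UTR were treated likewise for 16 microRNA families, with random lists matched on expression and 3′ UTR length. Positions, list medians and correlations were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

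Before the data were examined, 31 gene lists were fixed. They covered microRNA pathway proteins, microRNA host transcripts and published targets of let-7, miR-17/93/106, miR-21, miR-200, miR-15/16 and miR-34. They also covered cytosolic ribosomal proteins, other TOP mRNAs, translation initiation factors, aminoacyl-tRNA synthetases, replication-dependent histones, mitochondrially encoded mRNAs, nuclear respiratory chain genes, and very long coding mRNAs. Further lists held uORF-controlled and stress-response mRNAs, noncoding RNAs, endoplasmic reticulum chaperones, cytosolic chaperones, p53 targets, interferon-stimulated genes, cholesterol synthesis, glycolysis and hypoxia, and the proteasome. The last lists were mitotic genes, DNA replication genes, epithelial genes, mesenchymal genes, immediate early genes, and stromal and blood cell markers. Of these, 29 had enough measured members to be tested. The 13 mitochondrially encoded mRNAs had no row of their own among the analysed symbols and were not analysed here, and the stromal and blood cell list had 1 member in the fit.

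The genes named were set by a rule fixed before the data were examined. DICER1 came first. For heavy against light, these were the 12 largest folds in each direction among called protein-coding genes with a mean CPM of at least 20, a count in each library and the same direction in both gradients. For the genotypes, they were the 12 highest and 12 lowest by the smaller of the absolute log2 ratios in the 2 fractions, and for the shift, the 10 highest and 10 lowest. From each list up to 4 members per list with the largest absolute value among members with at least 50 counts were taken. Genes named outside this rule are marked where they appear. A few genes that the rule picked are not reported here.

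The fit was tested on simulated counts for the 13574 genes of the heavy and light comparison, with 200 genes changed: 73 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were called, with 7 false calls (3.89% of the calls). The simulation gave all genes a dispersion of 0.03 and the same heavy to light ratio in both gradients. Its error rate therefore does not carry over to the real calls. The percentile step was tested on 5000 simulated genes, where 7.50% of 200 unchanged lists stood apart and 46 of 50 lists shifted by 0.50 log2 units were found. Alternatives were DESeq2 1.42.0 size factors and its Wald test, library totals without TMM, other count filters, no gradient block, other prior counts, random lists matched on coding length too, and 2 or more microRNA sites. Leaving out a gradient leaves no residual degree of freedom and was not run. Alternatives added after the data were seen were a fit without the ribosomal RNA row and a stretch of the labelled knockout's ratios to the wild type spread. So were a computed mixture of the wild type libraries and microRNA sites matched on GC content. The GC matching used 3′ UTR length and GC content and left out expression.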

Results

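The series measured which mRNAs sit in heavy and in light polysomes of HCT116 cells, a human colorectal carcinoma line, with and without an altered gene for DICER1, the enzyme that cuts microRNA precursors. Polysomes are mRNAs loaded with several ribosomes, and a sucrose gradient separates them by the number of ribosomes. Each of the 4 groups had 1 library, so no difference between the genotypes has a replicate check. The count totals were 20933675 for wild type heavy, 19727010 for wild type light, 19238492 for labelled knockout heavy and 17457116 for labelled knockout light polysomes. Ribosomal RNA, counted in the row RNA45S5, took 2.61% of the counts in wild type heavy and 3.59% in wild type light polysomes, and 4.32% and 5.97% in the libraries labelled knockout. The exact 95% limits were 2.61 to 2.62%, 3.58 to 3.59%, 4.31 to 4.33% and 5.95 to 5.98%. Of 20 marker genes of fibroblasts, endothelium and blood, cells that a pure line should lack, COL1A1 alone had at least 50 counts in each library. The highest count of any other marker was 16, for VWF.

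DICER1 mRNA was about 2-fold higher in the libraries labelled Dicer1 knockout. The gene lies on chromosome 14 from 95086228 to 95158010 on the minus strand of GRCh38. Its counts were 500 in wild type heavy, 547 in wild type light, 925 in labelled knockout heavy and 889 in labelled knockout light polysomes. The log2 ratio of labelled knockout to wild type was 0.95 in heavy polysomes (counting interval 0.79 to 1.11) and 0.96 in light polysomes (0.81 to 1.11). The labels do not say where the gene was altered, and a count over the whole gene does not show whether it still encodes a working enzyme. The name "labelled knockout" is kept throughout, and every direction drawn between the genotypes rests on that label. DICER1 mRNA itself was not called toward either fraction, with a fitted log2 heavy to light ratio of 0.08 (edgeR quasi-likelihood test, adjusted p = 0.793, 2 gradients). With TMM scaling this lies near the median of all genes (-0.07) and does not show equal amounts in both fractions.

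The first comparison asked which mRNAs carry many ribosomes and which carry few. Long coding mRNAs lay mostly in heavy polysomes, and mRNAs of very small proteins lay in light ones. LMNA, a nuclear lamina protein, rose by a log2 ratio of 2.96 (SE 0.34, edgeR adjusted p = 1.79e-15) and FASN, the fatty acid synthase, by 2.94 (SE 0.34, adjusted p = 6.56e-16) in heavy over light polysomes. The largest enrichment in light polysomes was that of USMG5, a small subunit of ATP synthase, at -2.50 (SE 0.29, edgeR adjusted p = 4.40e-15). It was followed by SEC61G, a small subunit of the protein channel of the endoplasmic reticulum, at -2.26 (SE 0.29, adjusted p = 5.90e-13). TMSB4X, an actin-binding peptide, stood at -2.25 (SE 0.27, adjusted p = 1.25e-14).

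Further genes named for heavy polysomes were DCTN1 (log2 ratio 2.94), UNC45A (2.91), USP5 (2.90), NOC2L (2.90), SAFB (2.90), AARS (2.85), MVP (2.83), JUP (2.82) and DDB1 (2.79). Those named for light polysomes were SNRPG (-2.25), ATP5E (-2.19), RPS27L (-2.17), NDUFB1 (-2.16), LINC00998 (-2.13), OST4 (-2.11), MT1E (-2.11), TMEM14B (-2.11) and TMEM258 (-2.09). All of these passed edgeR's test. The coding sequences of the light group ran from 114 nucleotides for OST4 to 384 for MT1E, and those of the heavy genes given here from 1995 for LMNA to 7536 for FASN. The exons of OST4 overlap those of AGBL5 on the opposite strand over 33.3% of their length, and those of ATP5E overlap TUBB1 over 32.7%, so reads of these pairs cannot be told apart without the strand setting.

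Of 13574 genes tested, 8051 were called, 4074 toward heavy and 3977 toward light polysomes, and 2733 and 2382 of them differed at least 2-fold. The split depended on the scaling: with library totals alone, 38.9% of the called genes were higher in heavy polysomes against 50.6% with TMM, because the median log2 ratio of all genes moved from -0.07 to -0.30. Without the gradient as a block, 5040 genes were called. Across 10834 genes with at least 50 counts in each library, the heavy to light ratios of both gradients correlated with Pearson's r = 0.918 and Spearman's rho = 0.920. These are correlations across genes, which are not independent replicates. On the same side of 0 in both gradients lay 88.5% of genes.

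Coding length ordered the genes in both gradients. The median log2 heavy to light ratio was -1.24 in both for the 849 genes with coding sequences of up to 500 nucleotides. It was 0.07 in the wild type and 0.08 in the labelled knockout for 1000 to 1500 nucleotides, and 1.06 and 0.93 for the 467 genes above 5000 nucleotides. Spearman's rho across 10579 genes between coding length and the ratio was 0.50 in the wild type and 0.642 in the labelled knockout.

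**Figure D1:**
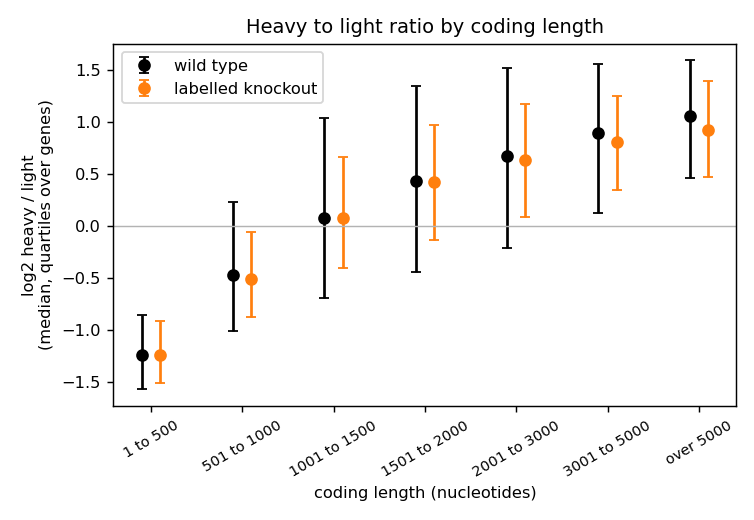
Median log2 heavy to light polysome ratio of genes in 7 classes of coding length (nucleotides), with bars from the lower to the upper quartile over genes, for the wild type gradient (black) and the labelled knockout gradient (orange). The medians climb from -1.24 in the shortest class of both gradients to 1.06 and 0.93 in the longest, and the bars of the labelled knockout are shorter.

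Several groups of genes lay mostly in heavy polysomes. All 20 aminoacyl-tRNA synthetases, the enzymes that charge tRNAs, were called toward heavy polysomes (20 adjusted over the list alone), with a median log2 ratio of 1.84. Of 44 very long coding mRNAs, 37 were called toward heavy polysomes (38 adjusted over the list alone), with a median of 1.23, among them PLEC at 2.67 and FLNA at 2.54. Cytosolic chaperones rose in 17 of 20 (median 1.74), among them the chaperonin subunits CCT2 at 2.40 and CCT5 at 2.40. Genes of DNA replication rose in 20 of 30 (median 1.25), such as MCM2 at 2.73 and MCM5 at 2.71. Genes of glycolysis and hypoxia rose in 21 of 28 (median 1.33), such as the pyruvate kinase PKM at 2.65 and the enolase ENO1 at 2.60. Mitotic genes rose in 18 of 27 (median 1.20), epithelial genes in 16 of 23 (median 1.15) and interferon-stimulated genes in 21 of 36 (median 0.86). Endoplasmic reticulum chaperones rose in 11 of 19 (median 0.94), proteasome subunits in 19 of 31 (median 0.92) and cholesterol synthesis genes in 13 of 24 (median 0.91).

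Toward light polysomes, 53 of 78 cytosolic ribosomal protein mRNAs were called and none toward heavy (56 adjusted over the list alone; median -0.97), with RPL39 at -1.86 and RPS21 at -1.78. Respiratory chain genes encoded in the nucleus were split: 34 of 53 were called light, such as NDUFB1, and 10 heavy, such as SDHA at 2.23 and ATP5B at 2.06 (median -1.13). Noncoding RNAs were called light in 20 of 23 (median -1.35), with the snoRNA host SNHG8 at -1.84 and the nuclear RNA MALAT1 at -1.62, and replication-dependent histones in 12 of 14 (median -1.47). Reads of ribosomal protein and histone genes may be shared with near-identical copies, so single members are uncertain. So are members whose exons overlap a gene on the opposite strand: MALAT1 over 77.8% of their length, CCT5 over 52.7%, SNHG8 over 40.3% and MCM2 over 32.4%. The exons of SDHA share 69.4% with a gene on the same strand. The 15 lists named in this and the preceding paragraph, 11 heavy and 4 light, passed camera with a preset correlation at an adjusted p under 0.05. With an estimated correlation none of the 29 lists did (smallest adjusted p = 0.789), nor by fry (smallest adjusted p = 0.276). Both of these tests rest on 1 residual degree of freedom and can hardly reach the threshold. Their outcome therefore decides neither for nor against the lists.

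The lists that did not pass camera split between the fractions. Of the TOP mRNAs outside the ribosomal proteins, 3 of 20 were called heavy, with EEF2 at 0.81, and 1 light, with 16 not called (median 0.39). Translation initiation factors were called heavy in 14 of 27 and light in 6 (median 0.78; camera adjusted p = 0.0751), with EIF4G1 at 2.26. Genes of the microRNA pathway were called heavy in 10 of 25 and light in 6 (median 0.08), with the precursor exporter XPO5 at 1.9. Of 10 microRNA host transcripts, 6 were called light and 2 heavy (median -1.07), with MIR100HG at -1.82 and MCM7 at 2.69. uORF-controlled and stress-response mRNAs had a median of -0.38, p53 targets -0.10, immediate early genes -0.21 and mesenchymal genes 0.65. The published microRNA target lists had medians of 0.03 for let-7, -0.17 for the miR-17 family, -0.25 for miR-21, 0.00 for miR-200, -0.04 for miR-15/16 and 0.31 for miR-34.

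**Figure D2:**
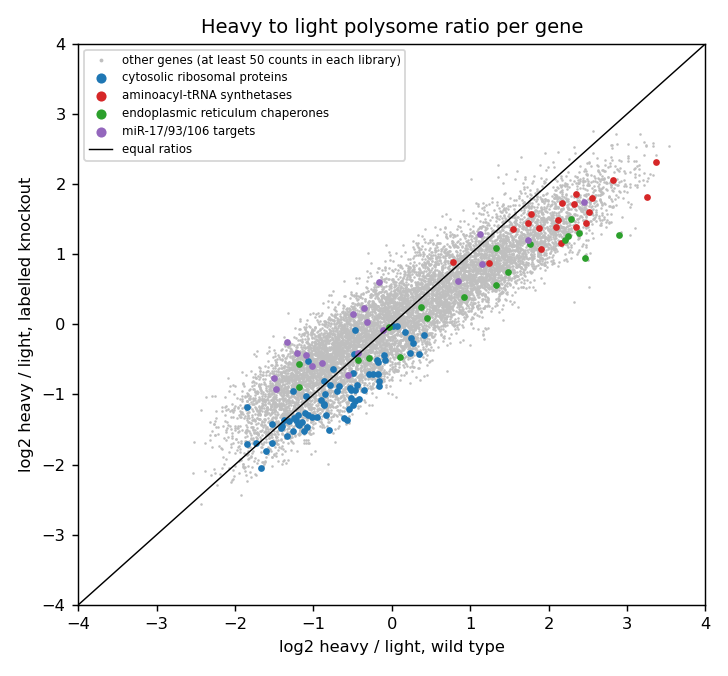
Log2 heavy to light polysome ratio of each gene in the wild type (x axis) and in the labelled knockout (y axis), for 10834 genes with at least 50 counts in each library (grey), with 4 gene lists in colour and the line of equal ratios. The cloud is flatter than the line (standard deviation over genes 1.17 in the wild type and 0.90 in the labelled knockout), aminoacyl-tRNA synthetases sit at the heavy end and ribosomal proteins at the light end.

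The second comparison set the labelled knockout against the wild type within each fraction. TM4SF18, a tetraspanin-like membrane protein, was nearly absent from the wild type libraries, with 2 counts in heavy and 4 in light polysomes. It had 567 and 859 counts in the libraries labelled knockout (log2 ratio 7.23, counting interval 5.81 to 8.65, and 7.36, 6.20 to 8.52). NPR3, the clearance receptor of natriuretic peptides, went the same way (6.55, 6.02 to 7.09, and 6.44, 5.97 to 6.91). ANXA10, an annexin, had 113 counts in wild type heavy and 115 in wild type light polysomes and 0 in both libraries labelled knockout. It was thus at least 36.0-fold lower in heavy and 32.0-fold lower in light polysomes with a floor of 3 counts per library. BST2, an interferon-induced membrane protein that tethers virus particles, was lower by log2 ratios of -5.41 in heavy (interval -5.89 to -4.93) and -5.00 in light polysomes (-5.38 to -4.61). GDI2, a regulator of Rab proteins and the most abundant of the named genes on this side, had 7943 and 4696 counts in the wild type and 838 and 645 in the labelled knockout.

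Further genes named as higher in the libraries labelled knockout were the adhesion molecule ICAM1 (log2 ratio 5.71 in heavy and 4.41 in light polysomes), the cytokine IL32 (4.32 and 5.25), ZBED2 (5.21 and 4.05) and the kinase DCLK1 (5.38, interval 4.10 to 6.66, and 3.96). On the same side were the keratin KRT23 (4.23 and 3.87), and KRTAP2-3 (3.59 and 4.39). So were the Wnt ligand WNT3A (3.79 and 3.32), SNTB1 (2.85 and 2.75) and AXIN2, a target and inhibitor of Wnt signalling (2.73 and 2.64). Those named as lower were CSTA (-4.51 and -4.45), the interferon-induced IFI27 (-4.10 and -3.99), ARMC4 (-4.09 and -3.96), and BHMG1 (-4.06 and -3.89). Also lower were FXYD3 (-3.70 and -3.84), MKX (-2.86 and -3.98), the protease inhibitor SLPI (-3.33 and -2.77), the guidance factor SEMA3A (-3.9 and -2.72), LURAP1L (-2.70 and -2.98) and GDI2 (-3.18 and -2.60). The exons of FXYD3 share 88.1% of their bases with a readthrough gene on the same strand, and those of AXIN2 share 30.9% with another such gene. Those of ICAM1 overlap ICAM4-AS1 on the opposite strand over 27.5%. KRTAP2-3 belongs to a family of near-identical genes and is uncertain.

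Among 10418 genes, 247 differed at least 2-fold in the same direction in both fractions, 122 higher and 125 lower in the libraries labelled knockout, and 0 differed 2-fold in opposite directions. In the heavy pair alone 325 were higher and 247 lower, and in the light pair 418 and 259. Independent lists of these sizes would share 13 higher and 6.14 lower genes. Both fractions of a genotype came from 1 gradient, so their overlap does not replicate the genotype. Across genes the log2 ratios of the pairs correlated with Pearson's r = 0.618 and Spearman's rho = 0.451.

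**Figure D3:**
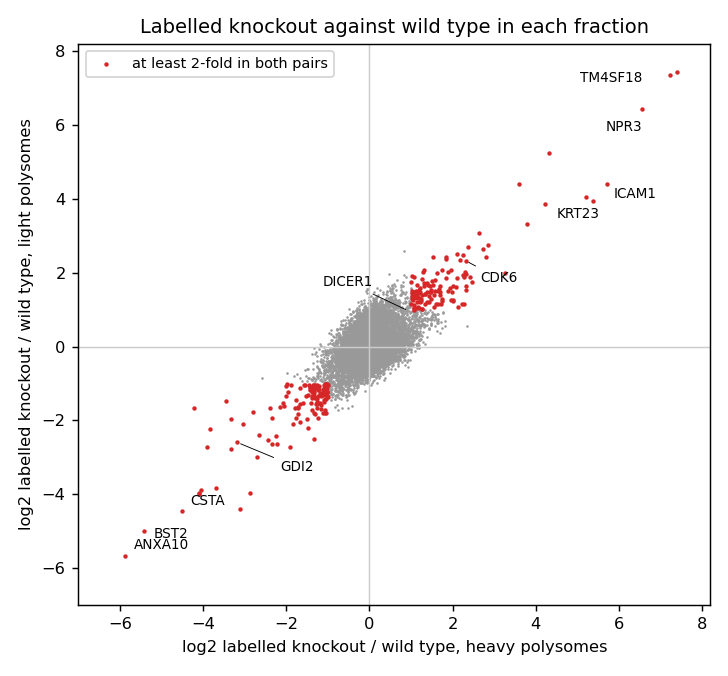
Log2 ratio of labelled knockout to wild type in heavy (x axis) and light polysomes (y axis) for 10418 genes, with a prior count of 2; red points are the 247 genes at least 2-fold apart in the same direction in both. DICER1 lies at 0.95 and 0.96, and ANXA10, at 0 counts in both libraries labelled knockout, is drawn at a position set by the prior count.

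Stress and growth-factor response genes were lower in the libraries labelled knockout. Immediate early genes, unstable mRNAs induced by growth signals, had a median log2 ratio of -0.80 in heavy and -0.70 in light polysomes, below all 10000 random lists in each (27 and 25 of 29 members below 0). FOSB stood at -2.79 and -1.79, and ATF3 at -2.15 and -1.63. uORF-controlled and stress-response mRNAs had medians of -0.70 and -0.84 (percentile 0.00 in each). SESN2 stood at -1.47 and -2.21, and TRIB3 at -1.37 and -1.73. Interferon-stimulated genes had medians of -0.57 (27 of 36 members below 0) and -0.31 (percentile 0.220), with IFITM1, whose exons share 52.5% with a gene on the same strand, at -3.03 and -2.11 and ISG15 at -1.38 and -0.90. Ribosomal protein mRNAs were slightly lower (medians -0.37 and -0.09, percentile 0.00 in each), and replication-dependent histones were lower in heavy polysomes (-0.59, percentile 0.12). Targets of p53 had medians of -0.21 (percentile 5.18) and -0.23 (percentile 1.06), with GDF15 at -1.98 and -0.71. Against a wild type light library mixed with 18.4% of the heavy one, ribosomal proteins and p53 targets no longer stood apart in light polysomes (medians 0.12, percentile 49.3, and -0.09, percentile 6.80). With random lists matched on coding length too, ribosomal proteins did stand below that mixed library's random lists (percentile 0.48). Targets of p53 did not (4.87).

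Very long coding mRNAs were higher, with medians of 0.40 in heavy and 0.75 in light polysomes (percentile 100 in each, 43 and 41 of 44 members above 0), with the spectrin SPTBN1 at 1.32 and 1.65. Over all genes this ratio rose with coding length (Spearman's rho 0.20 in heavy and 0.16 in light polysomes). Class medians rose from -0.17 and -0.11 at up to 500 nucleotides to 0.24 and 0.34 above 5000. The percentiles here matched expression only, so medians of long mRNAs, and of short ones such as ribosomal proteins, may partly follow length. Cholesterol synthesis genes had medians of 0.33 and 0.65 (percentile 100 in each), with the enzyme HMGCS1, whose exons overlap a gene on the opposite strand over 39.7%, at 0.86 and 1.33. Cytosolic chaperones had medians of 0.14 (percentile 99.9) and 0.75 (percentile 100), with HSPA1B, which is nearly identical to HSPA1A and so uncertain, at 1.32 and 2.07. Endoplasmic reticulum chaperones (0.12, percentile 98.4, and 0.81, percentile 100) and mitotic genes (0.12, percentile 99.7, and 0.73, percentile 100) were higher mainly in light polysomes, with MKI67 at 0.99 and 1.46. Against the mixed library, computed to allow for carry-over of heavy-polysome RNA, the medians in light polysomes were 0.31 for very long coding mRNAs (percentile 99.96), 0.41 for cholesterol synthesis (99.99), 0.41 for endoplasmic reticulum chaperones (percentile 99.8), 0.33 for mitotic genes (99.6) and 0.13 for cytosolic chaperones (55.1). Genes of glycolysis and hypoxia were lower in heavy polysomes (median -0.46, below all random lists) and stood at percentile 41.9 in light ones, where against the mixed library they were lower too (median -0.47, percentile 0.00). The glucose transporter SLC2A1 was higher in both (1.74 and 2.07). Translation initiation factors had medians of -0.21 and 0.09 and did not stand apart in either fraction. The same holds for microRNA host transcripts (-0.10 and -0.24) and mesenchymal genes (-0.14 and 0.14).

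Genes of the microRNA pathway and some published microRNA targets were higher in heavy polysomes of the labelled knockout. The pathway list had a median of 0.23 in heavy (percentile 99.2) and 0.13 in light polysomes (percentile 82.9). TNRC6A, a silencing scaffold, stood at 1.70 and 1.40, the decapping enzyme DCP2 at 1.65 and 1.15 and AGO1, an Argonaute protein, at 1.26 and 0.69. Published targets of miR-15/16 had medians of 0.57 (percentile 100) and 0.06 (percentile 60.2), with the cell cycle kinase CDK6 at 2.31 and 2.33. Those of the miR-17 family had 0.24 (percentile 99.0) and 0.06 (percentile 55.7), with ZNFX1 at 1.66 and 1.49 and VEGFA at -1.0 and -1.03. Targets of miR-200 had 0.28 (percentile 98.6) and 0.30 (percentile 93.7). Those of let-7 had 0.21 (percentile 96.3) and 0.13 (percentile 78.0), with NRAS at 1.17 and 0.34 and IGF2BP3, which overlaps MALSU1 on the opposite strand over 35.6% of its exons, at -1.77 and -1.45. Targets of miR-21 (0.00 and 0.05) and miR-34 (0.08 and 0.12) did not stand apart. The random lists for these published lists were matched on expression but not on 3′ UTR length. Over 10579 genes the ratio rose with 3′ UTR length in heavy polysomes (Spearman's rho 0.247) but not in light ones (0.00). The medians in heavy polysomes may therefore partly follow 3′ UTR length.

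Genes with sites for some microRNA families common in colon cells were slightly higher in the labelled knockout. On the mean of both fractions, genes with a 7-nucleotide 3′ UTR site stood above the upper limit of the random lists for 6 of 10 families common in colon cells (miR-15/16, miR-17, miR-19, miR-200b, miR-21 and miR-29) and for 1 of 6 families of other tissues (miR-124). Sites of miR-29 had the highest median, 0.12, over 2069 genes, and sites of let-7 stood at percentile 7.52, with a median of 0.06 over 1384 genes. The mean difference from matched random lists was 0.02 log2 units for the colon families and 0.00 for the others. An exact two-sided permutation test over 8008 regroupings of the families gave p = 0.0784 (adjusted p = 0.211 over 12 relations). The families differed in set size, from 244 genes for miR-451 to 3108 for miR-15/16. Larger sets cross the limits more easily at the same difference. The sets also share genes and were measured in the same libraries, so the families are not independent units for the permutation.

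**Figure D4:**
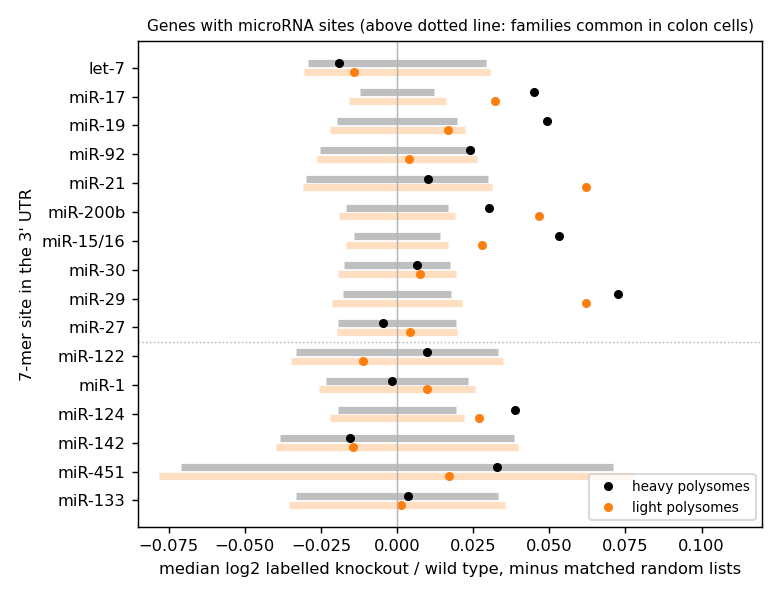
Median log2 ratio of labelled knockout to wild type of genes with a 7-nucleotide site for each of 16 microRNA families, minus the middle of the matched random lists, in heavy (black) and light polysomes (orange), with pale bars for the range between the lower and upper limit of the random lists. Sites of miR-29, miR-17, miR-15/16 and miR-200b lie to the right of the bars in both fractions, as do those of miR-124, a family of other tissues.

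The third comparison, the one that the series title names, asked whether mRNAs moved between heavy and light polysomes in the labelled knockout. CLU, PDIA3, HSP90B1 and VGF sat lighter there, and MFHAS1 and LEPR heavier. CLU, a secreted chaperone, had a log2 heavy to light ratio of 3.04 in the wild type and 1.28 in the labelled knockout, a shift of -1.76 (counting SE 0.04). PDIA3, a disulfide isomerase, shifted by -1.62 (SE 0.04), HSP90B1, the chaperone GRP94, by -1.51 (SE 0.02), and VGF, a secreted neuropeptide precursor, by -1.73 (SE 0.07). In the opposite direction, MFHAS1 went from -1.33 to 0.16, a shift of 1.49 (SE 0.16), and LEPR, the leptin receptor, from -2.37 to -1.03, a shift of 1.33 (SE 0.20).

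The other genes named as heavier in the labelled knockout were ASTN2 (shift 1.34), KIAA2018 (1.33), SUSD6 (1.32), RC3H2 (1.28), SVIP (1.27), ATP8B2 (1.25), FAM217B (1.25) and TAF4B (1.24). Those named as lighter were AK7 (-2.0), GFY (-1.98), MED27 (-1.50), PLBD2 (-1.49), TPP1 (-1.48) and FARSA (-1.44). The exons of PDIA3 overlap ELL3 on the opposite strand over 16.5% of their length, and those of TPP1 share 19.0% with a gene on the same strand. Against a wild type light library mixed with 18.4% of the heavy one, MFHAS1, ASTN2, KIAA2018, SUSD6, AK7 and GFY kept a 2-fold shift, and the other genes named for the shift did not.

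Among lists, published targets of the miR-17 family had a median shift of 0.34 toward heavy polysomes (percentile 99.8, 14 of 19 members above 0), with TNFRSF21 at 1.09, BCL2L11 at 0.80, E2F2 at 0.77 and TGFBR2 at 0.73. Their random lists were not matched on 3′ UTR length, with which the shift rose over 10579 genes (Spearman's rho 0.233). Genes with miR-17 sites stood at percentile 91.5 of the shift and at 3.40 with 2 or more sites. They stood at 99.94 with random lists matched on 3′ UTR length and GC content but not on expression. For the shift, sites of 2 of 10 colon families and of 2 of 6 others stood above the random lists (exact permutation of the mean differences, p = 0.95, adjusted p = 0.95 over 12 relations). With the GC matching 5 of 10 and 0 of 6 did (exact permutation of the mean differences, p = 0.232, adjusted p = 0.348). uORF-controlled mRNAs stood at 0.18 (percentile 99.7), and at percentile 96.7 after the labelled knockout's ratios were stretched to the wild type spread. TOP mRNAs outside the ribosomal proteins stood at -0.04 (percentile 99.0), and at percentile 96.5 against a computed mixture of the wild type libraries. Nuclear respiratory chain genes shifted toward light polysomes with a median of -0.50 (percentile 0.140, 49 of 53 members below 0), with SDHA at -1.40 and ATP5B at -1.35. Mesenchymal genes had a median of -0.56 (percentile 0.0200), with LOXL2 at -1.08. Further lists with lighter medians were aminoacyl-tRNA synthetases (-0.67, percentile 0.230), mitotic genes (-0.63, percentile 0.0800), endoplasmic reticulum chaperones (-0.57, percentile 0.880) and cytosolic chaperones (-0.57, percentile 2.28). The same held for the proteasome (-0.54, percentile 1.62), epithelial genes (-0.49, percentile 1.06), glycolysis and hypoxia (-0.45, percentile 1.8), interferon-stimulated genes (-0.44, percentile 0.01) and DNA replication (-0.43, percentile 0.680). After the same stretch, most of these no longer stood apart: synthetases (percentile 87.4), mitotic genes (15.6), endoplasmic reticulum chaperones (20.3), cytosolic chaperones (97.1), the proteasome (6.90), epithelial genes (32.5), glycolysis and hypoxia (29.9) and DNA replication (14.7). Interferon-stimulated genes did (1.68), but not against the mixture (7.45).

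Of 10834 genes, 355 shifted at least 2-fold, 98 toward heavy and 257 toward light polysomes, and 74.2% shifted less than 1.5-fold. The share toward heavy was 27.6% with TMM, 71.2% with library totals and 11.8% with DESeq2 size factors, because these scalings moved the median shift from -0.05 to 0.09 and to -0.12. Directions are therefore relative to the median gene. The standard deviation of the log2 heavy to light ratio over genes was 1.17 in the wild type and 0.90 in the labelled knockout. Of the genes called lighter, 256 of 257 had a wild type ratio above 0, and 97 of the 98 called heavier had one below 0. Against a wild type light library mixed with 18.4% of the heavy one, which gives the same narrowing at the heavy end, 56 genes shifted 2-fold. Aminoacyl-tRNA synthetases and cytosolic chaperones stood above the upper limit of the random lists, but mixing lowers the highest wild type ratios, such as theirs, most.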

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

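The tests of counting noise, of the computed mixtures of the wild type libraries, of the calls kept after the stretch and of random lists matched on GC content were chosen only after the results were seen. Directions between the genotypes rest on the label, since DICER1 mRNA was higher in the libraries labelled knockout.

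Ribosomal RNA, a row of the main fit that no fixed gene list covers, took 2.61% of counts in wild type heavy, 3.59% in wild type light, 4.32% in labelled knockout heavy and 5.97% in labelled knockout light polysomes, far above the limit that a count of 0 allows.

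For 15 named genes the ratio of labelled knockout to wild type lay on opposite sides of 0 in heavy and light polysomes, under each of TMM, library totals and DESeq2 size factors. With 1 library per group the difference was not tested. The log2 shifts were 1.49 for MFHAS1, 1.33 for LEPR, 1.32 for SUSD6, 1.27 for SVIP, 1.25 for ATP8B2 and 1.24 for TAF4B. They were -0.58 for MVP, -0.79 for DCTN1, -0.81 for JUP, -1.06 for AARS, -1.44 for FARSA, -1.49 for PLBD2, -1.50 for MED27, -1.51 for HSP90B1 and -1.62 for PDIA3. The median heavy to light ratio of let-7 targets was -0.44 in the wild type and 0.14 in the labelled knockout (median shift 0.20). That of miR-15/16 targets was -0.26 and 0.03 (median shift 0.16), and these differences were not tested either.

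The heavy to light ratios were less spread in the gradient labelled knockout. Counting noise is argued against, because the ratio of standard deviations stayed at 0.770 after the counting variance was subtracted. Carry-over of light-polysome RNA into the heavy library is argued against likewise. Its best mixture predicts 0.947 on the upper side where 0.694 was observed (bootstrap interval over genes 0.680 to 0.709). The bootstrap intervals resample genes of the same libraries and do not measure variation between gradients. Carry-over of heavy-polysome RNA into the light library stays open as a part of the narrowing: a mixture of 18.4% matches the upper side and predicts 0.869 on the lower side, inside the interval of 0.836 to 0.881 around the observed 0.862, and the bound first set for this test, under 0.9 on the lower side, was wrong because mixing narrows that side too. As the only difference between the gradients it is argued against, since mixing keeps the order of genes by their ratio. Spearman's rho with coding length across 10579 genes would then stay at the wild type value of 0.50, but was 0.642 in the labelled knockout. After a stretch of all ratios to the wild type spread 134 of the 355 shifted genes kept their call, and against the mixed library 37 did, so either may account for most of these calls; the count of shifted genes, which stayed at 0.938 of its value and was the bound first set, decides nothing because the stretch brings in other genes. A difference in translation between the genotypes, or between 2 gradients poured and collected separately, may narrow the ratios as well and was not tested.

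Endoplasmic reticulum chaperones, with PDIA3 and HSP90B1, had lighter medians in the labelled knockout. The list stood at percentile 20.32 after the stretch, and at 4.43 with random lists matched on coding length too, so the narrower gradient may account for it. The median shift went from -0.57 to -0.41 with the stretch, with 17 of 19 members still below 0. Against the mixed library it stood at percentile 6.42 with random lists matched on expression and at percentile 0.230 with lists matched on coding length too, so carry-over and a shift of this group cannot be told apart.

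Genes with sites for 6 of 10 microRNA families common in colon cells, and for 1 of 6 families of other tissues, stood slightly higher in the labelled knockout than matched random lists. If long 3′ UTRs or sequence composition of such genes were the cause, families of other tissues should stand apart as often as those common in colon cells. This holds only for sets of like size, since the range of the random lists is narrower for larger sets. Sets ran from 244 genes for miR-451, of other tissues, to 3108 for miR-15/16. The family of other tissues that stood above, miR-124, had the largest set of its group, 2072 genes. Because the sets share genes, the families are not independent units for the permutations that follow. The share above the upper limit of the random lists was 0.433 higher for the colon families, but an exact permutation of these shares gave p = 0.145 (adjusted p = 0.348 over 12 relations), so this explanation cannot be told apart from loss of microRNA repression. With random lists matched on 3′ UTR length and GC content but not on expression, 8 of 10 colon families and 1 of 6 others stood above. An exact permutation of these shares gave p = 0.0350 (adjusted p = 0.210 over 12 relations). Effects of the added GC matching and of the dropped expression matching cannot be told apart. The sites of let-7 did not go with the colon families, at percentile 7.52 and, with that matching, below the lower limit at percentile 2.32.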

How the results depend on the processing

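The fit without the ribosomal RNA row, the stretch, the mixed library and the GC matching were chosen only after the data were seen. For heavy against light polysomes, the number of called genes stayed within 1.5 times 8051 under 6 alternatives (6880 to 8218) and fell to 5040 without the gradient as a block, where the genotype difference enters the spread. Library totals gave 38.9% of calls toward heavy polysomes. For the genotypes, the count stayed between 193 and 249 under 5 alternatives. For the shift, the count stayed between 250 and 442 under 5 alternatives and was 56 against the mixed library. The share toward heavy was 71.2% with library totals, 11.8% with DESeq2 size factors and 16% with at least 200 counts in each library. Across 10834 genes the shift fell with mean expression (Spearman's rho -0.255), which a higher count filter selects for. Whether this caused the last share was not tested. Against the mixed library aminoacyl-tRNA synthetases (percentile 99.55) and cytosolic chaperones (percentile 99.81) stood apart on the heavy side. Mixing lowers the highest wild type ratios most, and these lists had the highest median heavy to light ratios (1.84 and 1.74). Their move may thus follow from the construction, and the cause was not tested. Of the list percentiles, 144 kept their side of the limits with library totals, and 115 with random lists matched on coding length too, where 13 no longer stood apart and 7 newly did. Library totals move all log2 ratios of a comparison by nearly the same amount, and the same random lists were used. Those percentiles could therefore hardly change. Of the percentiles of the light pair, 6 no longer stood apart against the mixed library and 3 newly did. Mixing adds most to mRNAs with high wild type ratios and so sets them lower in this pair by construction. Aminoacyl-tRNA synthetases moved to the lower side (percentile 0.28). With random lists matched on coding length too, the 16 synthetases with a known length did not stand apart there (percentile 13.9). After the stretch 9 shift percentiles no longer stood apart and 2 newly did, and against the mixed library 8 and 3. Of the microRNA site percentiles, 11 no longer stood apart and 5 newly did with 2 or more sites, and 4 and 10 with GC matching. The 116 values of named genes kept their sign with a prior count of 0.5, as did 92 with library totals. These genes were named for their large values, so a change of sign was unlikely from the start. Leaving out a gradient leaves no residual degree of freedom, so no test was possible. Depth limits the counts of shifted genes to genes with at least 50 counts in each library; the percentiles of the shift used all genes of the fit.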

Other observations

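The stretch, the mixed library, the GC matching and the tests on 3′ UTR length against that library and within expression classes were chosen only after the results were seen; the test of hydrophobic protein starts was written before its result.

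Some noncoding RNAs differed between the genotypes in both fractions. The snoRNA host transcripts SNHG8 (log2 ratio of labelled knockout to wild type -1.6 in heavy and -1.52 in light polysomes) and SNHG7 (-1.23 and -1.54) and the antisense transcript EPB41L4A-AS1 (-1.25 and -1.66) were lower in the libraries labelled knockout, while MALAT1 was higher (1.35 and 1.16). All of these overlap a gene on the opposite strand, over 40.3% of the exon length of SNHG8, 22.9% of SNHG7, 62.7% of EPB41L4A-AS1 and 77.8% of MALAT1, so their reads cannot be assigned with certainty. The noncoding list had medians of -0.11 (percentile 22.7) and -0.33 (percentile 0.320, and 18.6 against the mixed library), with 13 of 23 members below 0 in each fraction. With at least 200 counts summed over the libraries, 20 members were left. Their median in light polysomes against the mixed library was -0.24 (percentile 0.46), so that outcome depended on the count filter. MCM7, which carries microRNA hairpins of the miR-17 and miR-25 families in an intron, was lower in heavy polysomes (-1.37) and in light ones (-0.43).

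Respiratory chain mRNAs, mesenchymal genes and 19 published targets of the miR-17 family stood apart in the shift however the narrower gradient was treated. The median shift of the respiratory chain list was -0.50, and its percentile was 0.140, then 0.00 after the stretch and 0.00 against the mixed library. Both treatments were applied to all genes, though the shortest coding class was not narrowed (median -1.24 in both gradients). They therefore set mRNAs at the light end lighter by construction, and this list lies mostly there (median -1.13). The list's percentiles after the treatments add no support. For mesenchymal genes the percentiles were 0.0200, 0.0600 and 0.430, and for the published targets 99.8, 99.1 and 99.1. These random lists were not matched on 3′ UTR length. The shift rose with that length over all genes (Spearman's rho 0.233, and 0.216 against the mixed library), so the published targets may partly follow it. For genes with miR-17 sites the outcome depended on the setting. Their percentiles were 91.5, 82.1 and 88.6, and those of 925 genes with 2 or more sites 3.40, 0.390 and 0.230. Under GC matching, which left out expression, those of all genes with sites were 99.94, 99.96 and 99.99. Other families differed in direction. After the stretch and against the mixed library, sites of miR-15/16, miR-19, miR-27, miR-29 and, of other tissues, miR-122 stood above the random lists. Sites of miR-21 (percentiles 0.00 and 0.01), miR-200b (0.51 and 0.08) and miR-92 (0.99 and 0.13) stood below them. Sites of miR-124 stood above against the mixed library (99.7) but not after the stretch (92.4). Among single genes that kept a 2-fold shift against the mixed library were NME1 (-1.09, then -1.19), PRDX2 (-1.23, then -1.04), the proteasome subunit PSMD8 (-1.17, then -1.01), MFHAS1 (1.49, then 1.21) and ANKRD52 (1.06, then 1.20). Of these, NME1, PRDX2 and ANKRD52 were chosen after their values were seen. Ribosomal proteins stood at percentile 76.0 of the shift, and at 0.00 after the stretch and against the mixed library. The same construction may account for that move.

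A hypothesis was that genes with long 3′ UTRs, which hold more regulatory sites, sit heavier in the labelled knockout. Spearman's rho across 10579 genes between 3′ UTR length and the shift was 0.233, with 0.247 for the ratio of labelled knockout to wild type in heavy polysomes and 0.00 in light ones. Carry-over of heavy-polysome RNA is argued against as the cause, since rho was 0.216 against the mixed library, and so is a trend with expression level, since rho was at least 0.185 within each of 3 expression classes. The GC content of the transcripts had a rho of 0.0558 with the shift. The motifs in the 3′ UTRs may still contribute, and the relation rests on 1 library per group.

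A further hypothesis was that all mRNAs whose protein begins with a hydrophobic stretch, as secreted and membrane proteins do, shifted toward light polysomes together with the endoplasmic reticulum chaperones. A shared shift of all of them was argued against: 1691 such genes, the chaperones left out, had a median shift of 0.00 at percentile 57.33 of random lists matched on expression and coding length. A shift of a part of them stays open, since 48 of 251 genes shifted toward light polysomes had the hydrophobic start, 19.1% against 13.6% of those shifted toward heavy and 11.8% of all, and the set stood at percentile 4.74 against the mixed library. The same genes were higher in the labelled knockout in both fractions, with medians of 0.14 in heavy and 0.13 in light polysomes (percentile 100 in each), which the shift does not capture.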
